A study of Mus musculus with 12 samples.

How the data were processed

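Hippocampal total RNA from mice, in 12 libraries that form 4 groups of 3, was analysed: control or mutant mice, each treated with vehicle or delta-9-tetrahydrocannabinol (THC), the main psychoactive compound of cannabis. The labels call the mutant mice aDN-DISC1 and the series title speaks of an astrocyte-specific genetic vulnerability, and DISC1 is a scaffold protein linked to psychiatric illness. Ribosomal RNA was removed and the libraries were sequenced as paired ends, per the labels' protocols. The control libraries were placed by their titles, since their labels carry no genotype entry. The labels give no litter, cage, dose, age, sex or sequencing batch, and their numbers do not recur between groups, so no pairing was used. Whether the 3 libraries of a group come from separate mice is stated only as the number per group, so p-values measure the spread between these libraries.

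The authors deposited 1 table of expected counts per gene, unscaled for depth or length, with 23382 rows. The submitters' processing notes name CASAVA 1.8.4, FastQC, Bowtie2 2.2.2, RSEM 1.2.21 and edgeR 3.10.2 and the genome build mm10, and the column names in the file header show RSEM output on RefSeq transcripts. Between 27.2% and 29.4% of the values per library were not whole numbers, as RSEM shares ambiguous reads between genes. Members of gene families with near-identical copies, such as the haemoglobin and histone genes, are therefore uncertain. Whether strand was used in counting is not given in the sources used here, so overlapping antisense genes are uncertain too. The columns matched the 12 samples with 0 left over. Total expected counts were 33165903 to 41389957 per library, and the precision of low genes follows from these totals.

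Row names are RefSeq transcript accessions. A symbol was found for 23011 rows in the RefSeq annotation of GRCm38.p6 and for 129 more through GENCODE metadata, 7 rows held several symbols, and 235 rows without a symbol held 0.73% of the counts and kept their accession as name. The ribosomal precursor row held 0.22% to 0.32% of the counts. The list of mitochondrially encoded genes had no match among the symbols and was not analysed here. Coordinates are those of GRCm38.p6, the assembly of mm10.

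The expected counts were rounded to whole numbers, filtered with filterByExpr over the 4 groups (15802 genes kept) and scaled with TMM (factors 0.99 to 1.01). The main test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, R 4.3.3), with all 12 libraries in one model of 4 group means and 8 residual degrees of freedom. Contrasts gave 8 comparisons: the THC effect in each genotype, the genotype effect in each treatment, their interaction, both averaged effects, and mutant THC against control vehicle. P-values were adjusted over genes by Benjamini-Hochberg and 0.05 was the threshold. Log2 fold changes are given with standard errors (SE) taken from the F statistic, and levels as CPM (counts scaled to a library of 1e+06), mean ± SD over 3 libraries.

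Gene lists, 38 in all, were fixed before the data were examined, and 36 with at least 5 tested members were tested with camera of limma 3.58.1 at the preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Camera compares a list with the other genes, while fry asks whether a list's genes move one way on balance. A list score is the mean log2 CPM of the tested members with a prior count of 2. Genes were named by a rule fixed in the same way: the 12 largest rises and 12 largest falls among genes past the threshold at 1 CPM or more, or, where fewer than 3 passed, the 5 with the smallest p-values, said not to have passed. The genes Disc1, Srr, Cnr1, Gfap, Ptgs2, Nfkb1, Rela and Nfkbia were always given, and sex-linked genes per library as a check. List members named as examples were chosen after their values were seen.

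Where a group had 1 to 3 counts, the ratio of summed CPM is given with an exact 95% counting interval, which covers counting error only. Scores were compared by exact permutation within the other factor (400 arrangements, 2-sided). Libraries were checked for repeats with a chi-square per gene over pairs: the lowest of 66 pairs was 11.2, far above sampling noise, so all 12 count as separate libraries.

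The code was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 genes changed. Genes were drawn independently of each other, so differences between libraries that many genes share were absent. For the THC effect in control mice (15706 genes) the test recovered 56.1% of 1.5-fold, 74.6% of 2-fold and 93.8% of 4-fold changes. For THC in mutants, genotype under vehicle, genotype under THC and mutant THC against control vehicle it recovered 35.8%, 40.3%, 39.4% and 42.4% of 1.5-fold changes. For the interaction (15716 genes) the shares were 17.9%, 60.6% and 83.3%, and for the genotype effect averaged over treatments (15693 genes) 70.1%, 84.8% and 100%. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample weights, 3 other filters, only the 2 groups compared, estimation that is not robust, unrounded counts, the first residual principal component as a covariate, omission of sex-linked and haemoglobin genes, and each library left out. After seeing the data 3 were added: the choroid plexus score as a covariate, the choroid plexus and striatum scores together, and omission of mutant vehicle 3 and mutant THC 3.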

Results

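The study measured RNA in the hippocampus of control mice and of mice of a DISC1 mutant line (aDN-DISC1), after vehicle or THC, with 3 libraries in each of 4 groups. The series title places THC in adolescence and links it with the mutation through NF-kB and COX-2 signalling and memory. The comparisons below address what THC changed in each genotype, what the mutation changed under each treatment, and whether the effects differed. Total expected counts were 37942374, 37450401 and 39113364 in control vehicle 1 to 3, and 35834126, 41389957 and 35779460 in control THC 1 to 3. They were 38026124, 37015107 and 38954734 in mutant vehicle 1 to 3, and 33165903, 35333851 and 38871319 in mutant THC 1 to 3. The labels number the libraries, and vehicle libraries hold 6 to 11 while THC libraries hold 1 to 5 and 12, so the order of the libraries and the treatment cannot be told apart. Mutant vehicle libraries hold 8 to 10 in a run and control vehicle libraries 6, 7 and 11, so genotype under vehicle is not free of this order either.

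The 8 genes given in every comparison for their place in the study's question did not differ past the threshold in any of the 8 comparisons (edgeR quasi-likelihood test, Benjamini-Hochberg). Disc1 was at 2.26 ± 0.414 CPM in control vehicle, 2.48 ± 0.0829 in control THC, 2.54 ± 0.218 in mutant vehicle and 2.25 ± 0.811 in mutant THC (SD, n = 3), so the mouse Disc1 count did not mark the genotype. Ptgs2, which encodes COX-2, was at 30.9 ± 3.92, 34.3 ± 6.99, 29.9 ± 5.66 and 25.7 ± 9.68 CPM in the same order, with an interaction log2 fold change of -0.37 ± 0.36 (SE, adjusted p = 0.86). The NF-kB subunit genes Nfkb1 (-0.21 ± 0.08, adjusted p = 0.73) and Rela (-0.01 ± 0.10, adjusted p = 0.98) gave no interaction past the threshold. Srr, which encodes the D-serine synthesising enzyme bound by DISC1, was at 91.2 ± 4.24, 95.8 ± 6.67, 88.3 ± 2.22 and 97.1 ± 6.89 CPM. The astrocyte gene Gfap was at 443 ± 28.5, 391 ± 17.9, 500 ± 46 and 395 ± 96.9 CPM. Cnr1, the CB1 cannabinoid receptor gene, was at 335 ± 21.1, 322 ± 15.5, 325 ± 2.50 and 455 ± 201 CPM, the last mean resting on mutant THC 3 at 687 CPM beside 346 and 332 CPM. The Y-linked gene Ddx3y was at 80.8 to 137 CPM in the 12 libraries and the X-inactivation transcript Xist at 0 to 9 counts.

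Markers of neighbouring tissues differed between libraries of the same group. Ttr, the transthyretin gene that is abundant in the choroid plexus, was at 20.1 to 84.4 CPM in control vehicle 1 to 3, control THC 1 and 3, and mutant THC 2. It was at 5090 CPM in control THC 2, at 3639, 5241 and 9979 CPM in mutant vehicle, and at 5969 and 2857 CPM in mutant THC 1 and 3. The choroid plexus list score was 0.56 ± 0.60 in control vehicle, 2.27 ± 2.78 in control THC, 5.64 ± 0.90 in mutant vehicle and 3.74 ± 2.74 in mutant THC (SD, n = 3). Averaged over treatments it was higher in mutants by 3.27 (exact permutation p = 0.045, 0.16 when adjusted over the lists tested). Genes of striatal neurons stood apart in mutant THC 3, where the dopamine receptor gene Drd2 was at 52.1 CPM, the adenosine receptor gene Adora2a at 192 CPM and the enkephalin gene Penk at 531 CPM. Mutant vehicle 3 had 4.57, 16.3 and 60.7 CPM of these genes, and the other 10 libraries had at most 1.62 CPM of Drd2. The first principal component of log2 CPM held 43.5% of the variance and the second 16%. The first was at 8.01 to 46.62 in the libraries with high Ttr and at -35.54 to -19.77 in the others. The second was at 51.65 in mutant THC 3 and at most 5.07 elsewhere.

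**Figure D1:**
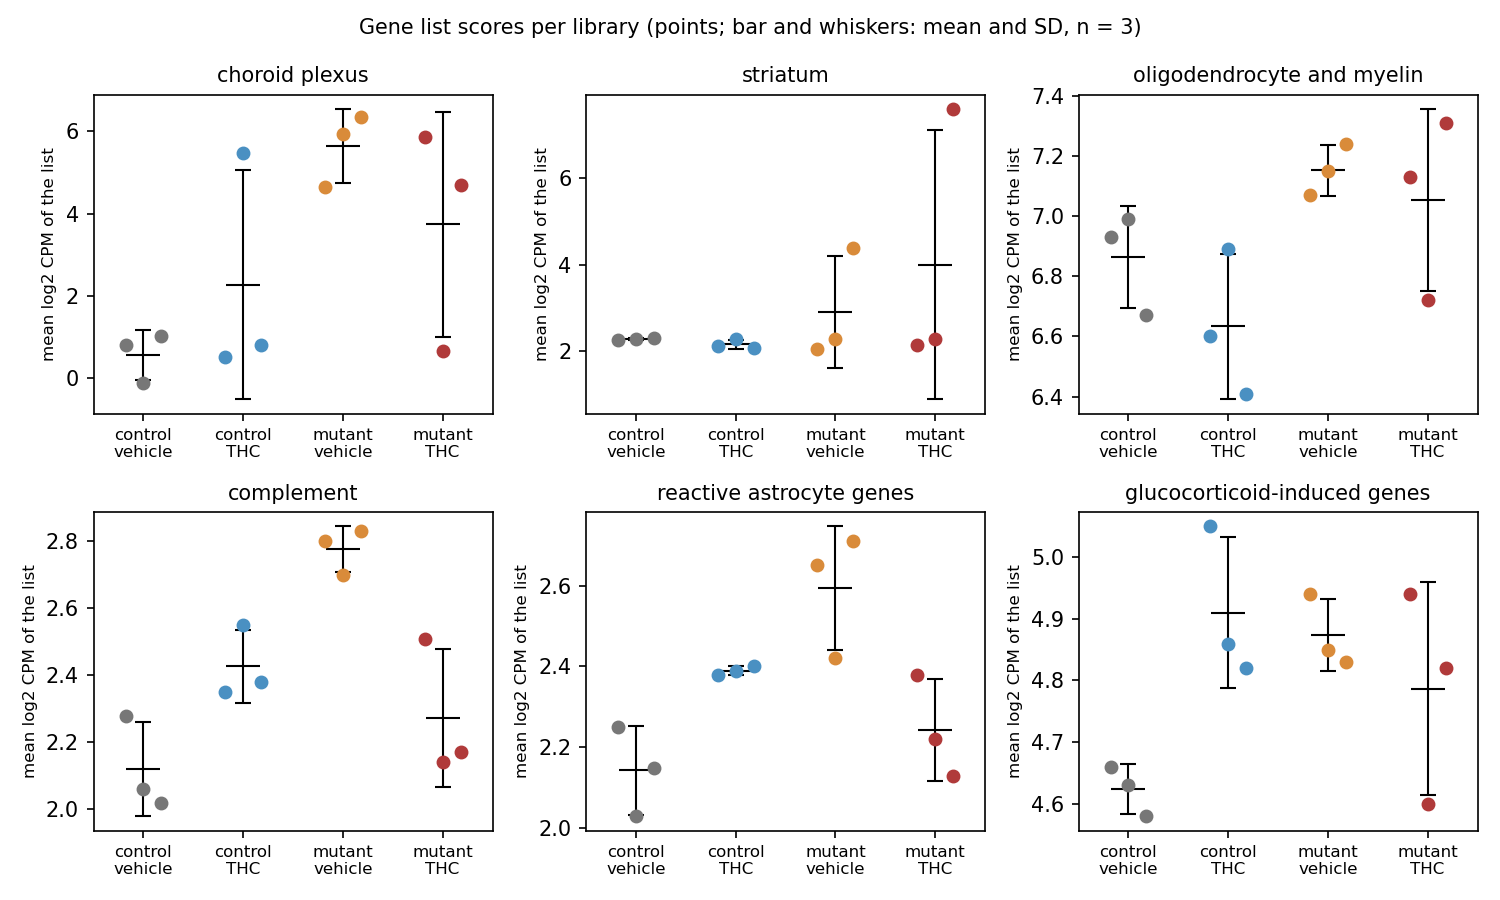
Mean log2 CPM of 6 gene lists (vertical axes) in each library of the 4 groups (horizontal axes). Points are libraries, bars and whiskers are the mean and SD of 3 libraries. The choroid plexus score was high in control THC 2 and in 5 mutant libraries, and the striatum score was highest in mutant THC 3.

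THC in control mice raised or lowered no single gene past the threshold, and glucocorticoid-induced genes went up as a list by camera at the preset correlation but not with an estimated correlation (adjusted p = 0.17). Ddit4, an inhibitor of mTOR signalling induced by stress, was at 37.4 ± 4.49 CPM in vehicle and 55.3 ± 2.33 in THC (SD, n = 3, log2 fold change 0.56 ± 0.08, adjusted p = 0.55 by edgeR). Sgk1, a glucocorticoid-regulated kinase gene, was at 90.2 ± 8.39 and 171 ± 22.8 CPM (0.92 ± 0.24), Fkbp5, a co-chaperone of the glucocorticoid receptor, at 51.3 ± 3.25 and 69.9 ± 7.20 CPM (0.45 ± 0.12), and Nfkbia, the NF-kB inhibitor gene, at 29.4 ± 2.96 and 38.7 ± 2.58 CPM (0.40 ± 0.11). The other genes with the smallest p-values were Tubb4a, a tubulin gene, at -0.32 ± 0.05, and Acsf2, Zfp568 and Zfp212 at 0.57 ± 0.10, 0.46 ± 0.09 and 0.38 ± 0.08, and none of them passed. Sgk1 was at 179 ± 34.2 CPM in mutant vehicle and 182 ± 63.1 in mutant THC. In the same order Ddit4 was at 49.2 ± 2.74 and 54.4 ± 2.95 CPM. Nfkbia was at 36.8 ± 2.63 and 38.3 ± 5.40 CPM and Fkbp5 at 54.9 ± 7.83 and 57.1 ± 6.52. Mutant vehicle was thus nearer control THC than control vehicle in Sgk1, Ddit4 and Nfkbia, but not in Fkbp5. Ddit4, Sgk1 and Fkbp5 were named for their values in control THC against control vehicle. Both groups are set against the same control vehicle libraries here, so this likeness is partly built in. The glucocorticoid-induced list score was 4.63 in control vehicle, 4.91 in control THC, 4.87 in mutant vehicle and 4.79 in mutant THC.

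Of the 20 tested glucocorticoid-induced genes, 7 rose and 0 fell when adjusted over the list alone, 0 passed over all genes tested, and the median log2 fold change was 0.23 (camera adjusted p = 1.9e-11, with an adjusted p = 0.17 with an estimated correlation). Reactive astrocyte genes were higher with a median of 0.25, and 2 of 31 rose when adjusted over the list alone (camera adjusted p = 8.9e-05, adjusted p = 0.32 with an estimated correlation). Cp, the ceruloplasmin gene, was at 0.54 ± 0.12 in that list and Gfap at -0.18 ± 0.15. The separate list of astrocyte markers was called by camera at the preset correlation with a median of -0.10. Its call was lost without control vehicle 1 (median -0.03) or control THC 2 (-0.06). Complement genes had a median of 0.29, with 1 of 16 past the threshold over the list alone (camera adjusted p = 5.0e-04, adjusted p = 0.32 with an estimated correlation), and Serping1, the C1 inhibitor gene, was at 0.74 ± 0.19. Mural and meningeal genes had the same median of 0.29 with 0 of 15 past the threshold over the list alone (camera adjusted p = 0.0031, adjusted p = 0.38 with an estimated correlation). Their call was lost without control THC 2 (median 0.12), and the median was 0.16 without control vehicle 2 and 0.15 without control THC 1. Endothelial markers had a median of 0.14 and 1 of 16 rose over the list alone, with Vwf at 0.85 ± 0.19 (camera adjusted p = 0.0011, adjusted p = 0.32 with an estimated correlation). Another member, the tight junction gene Cldn5, was at -0.22 ± 0.10. The oligodendrocyte and myelin list had a median of -0.20, all 19 members were below 0 and 0 passed over the list alone (camera adjusted p = 5.5e-06, adjusted p = 0.47 with an estimated correlation). Mbp, the myelin basic protein gene, was at -0.36 ± 0.19. The choroid plexus list had a median of 3.5 over 16 members, which was 0.15 without control THC 2, and 0 members passed over the list alone (camera adjusted p = 2.4e-06, adjusted p = 0.47 with an estimated correlation). The choroid plexus call was lost without control THC 2. The complement median was 0.18 without control THC 2, 0.19 without control vehicle 2, 0.48 without control vehicle 1 and 0.45 without control THC 3, and the myelin median was -0.36 without control THC 2 and -0.11 without control THC 3. In all, camera called 15 of 36 lists (9 up, 6 down). The edgeR test called 0 of 15802 genes, with 1106 at an unadjusted p under 0.05 where chance gives 790, while DESeq2 called 11 and limma-voom 0. Groups did not overlap for 16.4% of the genes, where chance gives 10% for 3 against 3.

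In mutant mice no single gene passed the threshold after THC. Complement and reactive astrocyte genes were lower as lists by camera at the preset correlation but not with an estimated correlation (adjusted p = 0.11 for each), beside lower choroid plexus and meningeal markers (medians -0.99 and -0.52). C3, the central complement component gene, was at 4.73 ± 0.669 CPM in vehicle and 1.54 ± 0.174 in THC (SD, n = 3, log2 fold change -1.62 ± 0.36, adjusted p = 0.81 by edgeR). Serping1 was at 11.3 ± 2.34 and 7.02 ± 1.52 CPM (-0.69 ± 0.19) and Ptges, which encodes the prostaglandin E synthase downstream of COX-2, at 5.23 ± 0.473 and 3.44 ± 0.379 CPM (-0.60 ± 0.14). The genes with the smallest p-values, none of which passed, were Ifitm1, an interferon-induced membrane protein gene (-1.0 ± 0.16), Emilin1, an extracellular matrix gene (-0.95 ± 0.17), Cd74, the class II invariant chain gene (-1.33 ± 0.27), Cnmd (-1.50 ± 0.32) and Cbln3 (-1.82 ± 0.39).

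Complement genes had a median of -0.46, and 3 of 16 fell when adjusted over the list alone while 0 passed over all genes (camera adjusted p = 6.5e-08, adjusted p = 0.11 with an estimated correlation). Reactive astrocyte genes had a median of -0.26 and 6 of 31 fell over the list alone (camera adjusted p = 8.8e-09, adjusted p = 0.11 with an estimated correlation), among them Gbp2 at -0.49 ± 0.11. The list of NF-kB targets and subunits had a median of -0.22 with 0 of 25 past the threshold over the list alone (camera adjusted p = 0.0036, adjusted p = 0.11 with an estimated correlation), and its smallest p-values were those of Icam1, an adhesion molecule gene (-0.50 ± 0.14), and the transcription factor gene Irf1 (-0.39 ± 0.13). The prostanoid and leukotriene pathway had a median of -0.18 and 1 of 27 fell over the list alone (camera adjusted p = 0.0036, adjusted p = 0.25 with an estimated correlation) and its call was lost without mutant vehicle 1 (median -0.09, adjusted p = 0.057), while the median was -0.09 without mutant vehicle 3 and -0.03 without mutant THC 3. Interferon response genes had a median of -0.22 with 0 of 27 past the threshold over the list alone (camera adjusted p = 1.9e-05, adjusted p = 0.17 with an estimated correlation). Endothelial markers were higher on balance with a median of 0.05, and 3 rose and 1 fell over the list alone (camera adjusted p = 0.013, adjusted p = 0.30 with an estimated correlation). Cldn5, a tight junction gene, was at 0.40 ± 0.10 and Vwf at -0.04 ± 0.19. The choroid plexus list moved the same way as complement, with a median of -0.99, and the mural and meningeal list had a median of -0.52 (adjusted p = 0.77 and 0.28 with an estimated correlation). The striatum list had a median of 2.59 (adjusted p = 0.77 with an estimated correlation). Without mutant THC 3 camera called it in the opposite direction (median -0.95, adjusted p = 8.1e-06). The endothelial call was lost without mutant vehicle 1 (median 0.12) or mutant THC 1 (0.01), with medians of 0.03 without mutant vehicle 2 and 0.10 without mutant THC 3. The choroid plexus call was lost without mutant THC 2 (median -0.46), and its median was -2.05 without mutant THC 1 and -0.61 without mutant vehicle 3. The mural and meningeal median was -0.19, -0.26 and -0.27 without mutant vehicle 1, mutant THC 2 and mutant THC 3, and that of NF-kB genes was -0.13 without mutant THC 3. Camera called 10 lists, 2 up and 8 down. EdgeR called 0 genes, and 3 without mutant THC 1, with 906 at an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. Groups did not overlap for 8.47% of the genes, where chance gives 10%.

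**Figure D2:**
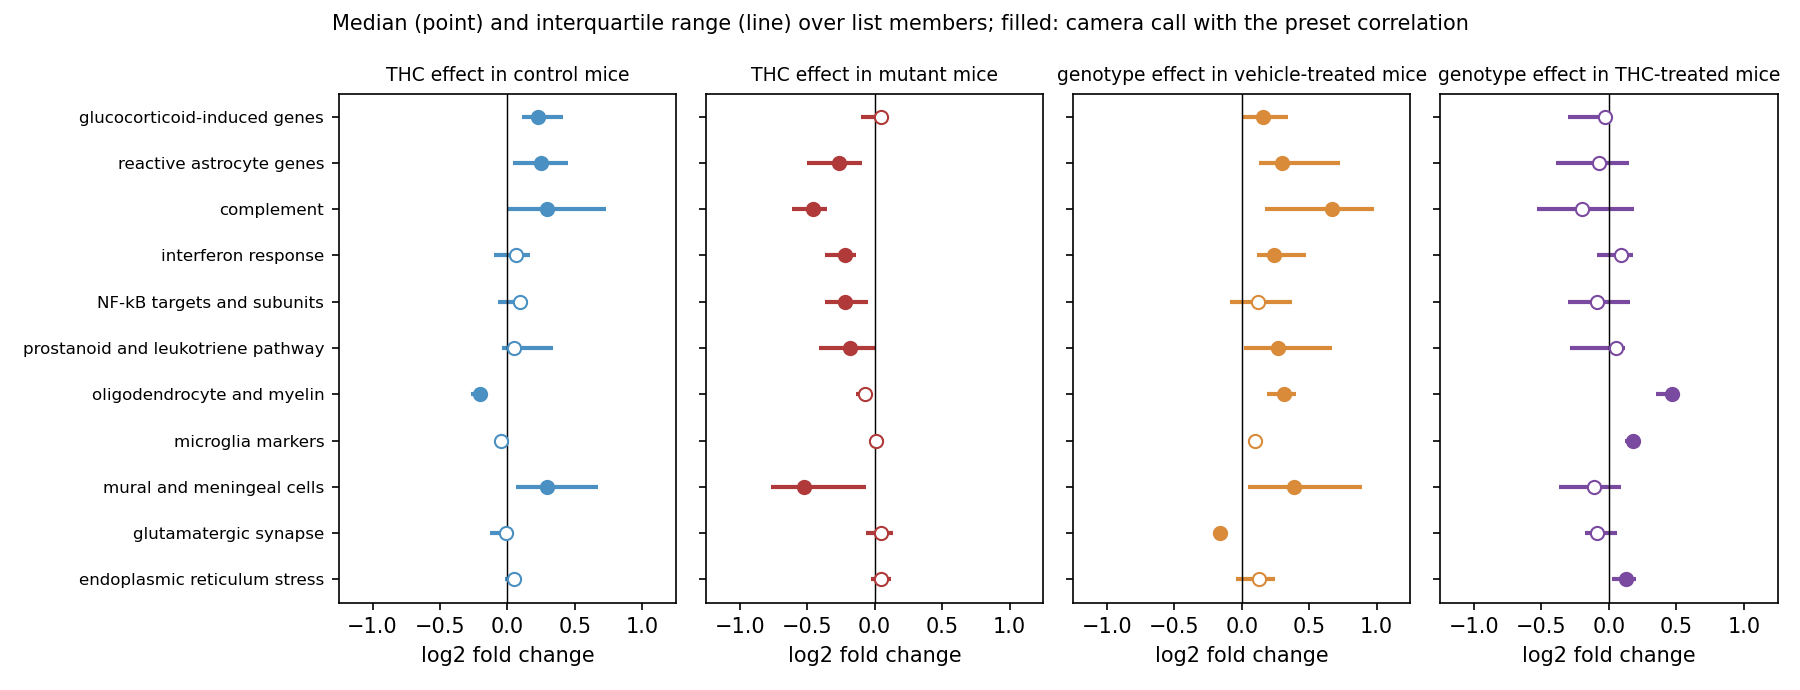
Median log2 fold change of 11 gene lists (points) and the interquartile range over their members (lines) in the 4 comparisons that change 1 factor at a time. Filled points passed camera with the preset correlation, and none passed with an estimated correlation. Complement genes had medians of 0.29 and -0.46 for THC in control and mutant mice.

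Mutant vehicle mice differed from control vehicle mice by 1 gene past the threshold, Prm1, and by lists that camera called at the preset correlation but not with an estimated one, among them higher complement, reactive astrocyte, interferon and choroid plexus genes (adjusted p = 0.18, 0.23, 0.27 and 0.27 with an estimated correlation). Prm1 encodes protamine 1, a sperm chromatin protein, and lies on chromosome 16 from 10796332 to 10796823 (GRCm38.p6, NM_013637). It had 111, 87 and 61 counts in the 3 mutant vehicle libraries and 0, 0 and 1 counts in the 3 control vehicle libraries, a ratio of 258 (95% exact counting interval 45.8 to 10212, edgeR adjusted p = 0.017). The next smallest p-values, none past the threshold, were those of Cp at 20.6 ± 2.51 and 34.0 ± 2.51 CPM (SD, n = 3, log2 fold change 0.73 ± 0.12, adjusted p = 0.16), the complement-related protease gene C1rl (1.62 ± 0.27), Nt5dc2 (0.97 ± 0.16) and Cd74 (1.62 ± 0.28). The Prm1 call was lost when any of control vehicle 1, 2 and 3, control THC 1 or mutant vehicle 1 was left out, with adjusted p-values of 0.0054 to 0.32 and log2 fold changes of 7.11 to 9.40 over the 12 omissions.

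Complement genes had a median log2 fold change of 0.67, and 5 of 16 rose when adjusted over the list alone (camera adjusted p = 4.0e-08, adjusted p = 0.18 with an estimated correlation). C3 was at 1.5 ± 0.386 and 4.73 ± 0.669 CPM (1.66 ± 0.36). Of the reactive astrocyte genes 11 of 31 rose over the list alone with a median of 0.30 (camera adjusted p = 4.0e-08, adjusted p = 0.23 with an estimated correlation), and Vim, the intermediate filament gene vimentin, was at 42.2 ± 5.67 and 61.1 ± 6.29 CPM (0.53 ± 0.10). Interferon response genes had a median of 0.24 and 6 of 27 rose over the list alone (camera adjusted p = 7.5e-05, adjusted p = 0.27 with an estimated correlation). Trim30a was at 0.85 ± 0.16. The prostanoid and leukotriene pathway had a median of 0.27 and 0 of 27 past the threshold over the list alone (camera adjusted p = 0.0028, adjusted p = 0.27 with an estimated correlation). Ptges was at 0.48 ± 0.14 and the prostanoid exporter gene Abcc4 at 0.78 ± 0.22. Glutamatergic synapse genes had a median of -0.16, with 27 of 29 below 0 and 0 past the threshold over the list alone (camera adjusted p = 6.7e-05, adjusted p = 0.27 with an estimated correlation). Beside these lists the choroid plexus list had a median of 5.51, with 16 of 16 members up over the list alone (camera adjusted p = 3.7e-15, adjusted p = 0.27 with an estimated correlation). Its members Wfdc2 and Ttr were at 5.66 ± 1.58 and 6.90 ± 2.26. Ependymal genes had a median of 1.44, blood genes 0.79, mural and meningeal genes 0.39 and myelin genes 0.31, the last with the transferrin gene Trf at 0.49 ± 0.20 (adjusted p = 0.27, 0.27, 0.27 and 0.48 with an estimated correlation). Lower lists included nuclear-retained RNAs, with a median of -0.45, CA1 markers, with -0.42, and neocortex layers, with -0.28 (adjusted p = 0.48, 0.40 and 0.27 with an estimated correlation). The call of nuclear-retained RNAs was lost without control vehicle 2 (median -0.15) or mutant vehicle 1 (-0.46) and that of CA1 markers without mutant vehicle 3 (-0.26). The neocortex call was lost without control vehicle 3 (-0.19), and its median was -0.13 without mutant vehicle 3. The interferon median was 0.14 without control vehicle 2. Camera called 17 lists (11 up, 6 down), and fry called 3, complement (adjusted p = 0.014), reactive astrocyte (0.02) and interferon response genes (0.041). At an unadjusted p under 0.05 there were 2815 genes where chance gives 790, and groups did not overlap for 28.0% of genes. DESeq2 called 768 genes (623 higher, 145 lower), edgeR on the 2 groups alone 523, and limma-voom 0. EdgeR called 6 genes without mutant THC 1 and 2 without mutant vehicle 2, and 0 with the choroid plexus score as a covariate, an alternative chosen after seeing the data. With that covariate the complement median was 0.21, the reactive astrocyte median 0.34, the glutamatergic synapse median 0.01, the myelin median -0.10, the prostanoid median 0.16 and the interferon median 0.24. The complement, reactive astrocyte, prostanoid and interferon calls were kept at the preset correlation (camera adjusted p = 1.7e-06, 1.8e-09, 0.0059 and 0.0054). With the mural and meningeal score as a covariate the complement median was 0.22 and the reactive astrocyte median 0.33, with both calls kept (camera adjusted p = 0.018 for each). The prostanoid and interferon calls were lost with it (medians 0.13 and 0.14, camera adjusted p = 0.63 and 0.13).

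**Figure D3:**
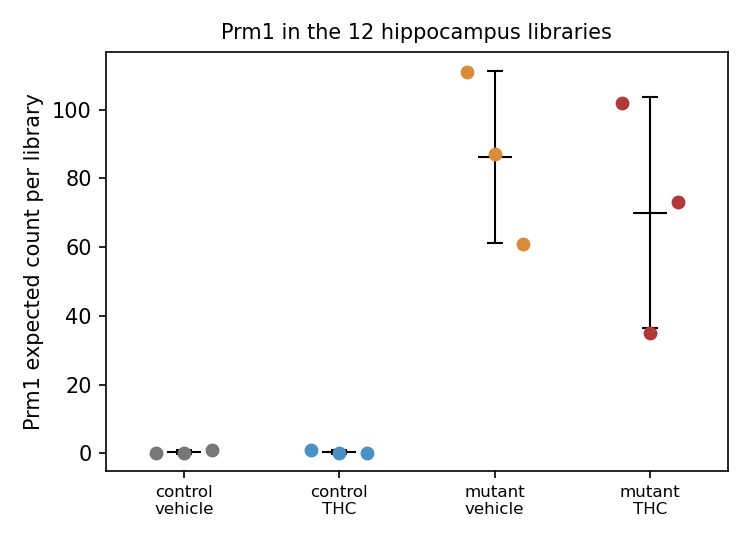
Expected counts of Prm1 (vertical axis) in each of the 3 libraries of the 4 groups (horizontal axis), with the group mean and SD. The 6 mutant libraries had 35 to 111 counts and the 6 control libraries 0 or 1.

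Under THC the genotypes again differed in Prm1 alone. Myelin, microglia and striatum genes were higher as lists by camera at the preset correlation but not with an estimated correlation (adjusted p = 0.61 for each). Prm1 had 102, 35 and 73 counts in mutant THC and 1, 0 and 0 in control THC, a ratio of 222 (95% exact counting interval 39.4 to 8798, edgeR adjusted p = 0.025). Nptxr, the neuronal pentraxin receptor gene, was at 228 ± 11.2 and 116 ± 15.8 CPM (SD, n = 3, log2 fold change -0.98 ± 0.14, adjusted p = 0.18), followed by Rabl3 (0.46 ± 0.08) and Slc27a3 (-0.65 ± 0.12), none past the threshold. The Prm1 call held in 3 of 12 omissions of a library, without mutant vehicle 1, mutant vehicle 3 or mutant THC 2 (adjusted p of 0.0064 to 0.34, log2 fold changes of 6.84 to 9.21 over the 12 omissions).

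The oligodendrocyte and myelin list had a median of 0.47, and 14 of 19 members rose when adjusted over the list alone (camera adjusted p = 4.9e-16, adjusted p = 0.61 with an estimated correlation). Ugt8a, which makes a main myelin lipid, was at 84.1 ± 13 and 136 ± 31.5 CPM (0.70 ± 0.18), and Cnp at 0.51 ± 0.16. Microglia markers had a median of 0.18, all 19 above 0 and 0 past the threshold over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.61 with an estimated correlation). The complement gene C1qa was at 50.8 ± 2.62 and 58.5 ± 3.29 CPM (0.20 ± 0.07). Nuclear genes of oxidative phosphorylation had a median of 0.08 with 0 of 32 past the threshold over the list alone (camera adjusted p = 1.9e-04, adjusted p = 0.68 with an estimated correlation). Beside them the striatum list had a median of 3.61 with 12 of 12 up over the list alone, which was 0.06 without mutant THC 3 (camera adjusted p = 1.2e-05, adjusted p = 0.61 with an estimated correlation), and Drd2 and Gpr6 were at 4.26 ± 1.49 and 5.34 ± 1.83, with Gpr6 at -0.09 without mutant THC 3. The choroid plexus list had a median of 0.81, from -0.22 without mutant THC 1 to 4.44 without control THC 2 (adjusted p = 0.72 with an estimated correlation). Dentate granule neuron markers had a median of -0.51 with 0 of 10 past the threshold over the list alone (camera adjusted p = 5.0e-04, adjusted p = 0.61 with an estimated correlation). The choroid plexus call was lost without control THC 1, control THC 3 or mutant THC 1 (medians 0.27, 0.30 and -0.22), and the dentate call without control THC 3 or mutant THC 1 (-0.23 and -0.40). The dentate median was -0.87 without mutant THC 2 and -0.27 without mutant THC 3. The oxidative phosphorylation call was lost without mutant THC 1 (median 0.05) and its median was 0.15 without mutant THC 2, while that of myelin was 0.31 without mutant THC 3. Camera called 11 lists, 9 up and 2 down, and 6 without mutant THC 1. EdgeR counted 1419 genes at an unadjusted p under 0.05, DESeq2 called 7 genes and limma-voom 0. Groups did not overlap for 10.5% of genes.

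The interaction asked whether THC acted differently in mutants, and 0 genes passed the threshold. Camera called 19 lists at the preset correlation and 0 with an estimated correlation. Cp (log2 fold change -0.97 ± 0.17), Cd74 (-2.18 ± 0.39), Slc35g1 (-0.97 ± 0.18) and Cped1 (-1.77 ± 0.32) were among the genes with the smallest p-values (adjusted p = 0.48 by edgeR for each). Complement genes had a median of -0.80 and 6 of 16 fell when adjusted over the list alone (camera adjusted p = 2.7e-10, adjusted p = 0.078 with an estimated correlation). Serping1 was at -1.43 ± 0.27 and C3 at -2.45 ± 0.51. Reactive astrocyte genes had a median of -0.51 and 7 of 31 fell over the list alone (camera adjusted p = 7.7e-12, adjusted p = 0.078 with an estimated correlation). These were the 2 lists that fry called, each with an adjusted p = 0.036. Glucocorticoid-induced genes had a median of -0.22 and 3 of 20 fell over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.17 with an estimated correlation). Plin4, a lipid droplet gene, was at -1.72 ± 0.48. NF-kB targets and subunits had a median of -0.29 and 0 of 25 past the threshold over the list alone (camera adjusted p = 0.0069, adjusted p = 0.16 with an estimated correlation). The cytokine gene Csf1 was at -0.37 ± 0.12. The prostanoid and leukotriene pathway had a median of -0.35 and 0 of 27 past the threshold over the list alone (camera adjusted p = 0.0019, adjusted p = 0.19 with an estimated correlation). Ptges was at -0.58 ± 0.20. Mural and meningeal genes had a median of -0.81, with the collagen gene Col1a2 at -1.61 ± 0.40, and choroid plexus genes one of -4.60 (adjusted p = 0.17 and 0.28 with an estimated correlation). The choroid plexus median was -1.0 without control THC 2, the mural and meningeal one -0.53 without mutant vehicle 1, the glucocorticoid one -0.11 without control THC 1 and the NF-kB one -0.19 without mutant vehicle 3. The prostanoid median was -0.19, -0.19, -0.22 and -0.21 without control THC 2, mutant vehicle 3, mutant THC 2 and mutant THC 3. The edgeR test counted 1041 genes at an unadjusted p under 0.05, and 10 genes were called without mutant THC 1. DESeq2 called 32 genes, 1 higher and 31 lower, and limma-voom 0.

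Averaged over genotypes, THC went with lower Tubb4a and higher Ddit4, the latter mainly in controls, though no gene passed the threshold. Tubb4a was at 175 ± 3.54 and 140 ± 2.13 CPM in controls and 177 ± 8.30 and 155 ± 8.04 CPM in mutants (SD, n = 3, log2 fold change -0.26 ± 0.04, adjusted p = 0.45 by edgeR). Ddit4 was at 0.35 ± 0.06, Ndp, which encodes norrin, at -0.35 ± 0.07, the hyaluronan synthase gene Has2 at -0.73 ± 0.15 and Acsf2 at 0.33 ± 0.07. By genotype, Ddit4 was at 0.56 ± 0.08 in controls and 0.14 ± 0.08 in mutants. Acsf2 was at 0.57 ± 0.10 in controls and 0.10 ± 0.10 in mutants. Endothelial markers had a median of 0.09, and 3 rose and 1 fell of 16 when adjusted over the list alone (camera adjusted p = 1.7e-05, adjusted p = 0.25 with an estimated correlation). The angiopoietin receptor gene Tek was at 0.26 ± 0.06. Glucocorticoid-induced genes had a median of 0.12 and 1 of 20 rose over the list alone (camera adjusted p = 5.4e-06, adjusted p = 0.40 with an estimated correlation). Fkbp5 was at 0.25 ± 0.08, with 0.45 ± 0.12 in controls and 0.06 ± 0.12 in mutants. The score of this list went from 4.63 to 4.91 in controls and from 4.87 to 4.79 in mutants. The oligodendrocyte and myelin list had a median of -0.15 with 18 of 19 below 0 and 0 past the threshold over the list alone (camera adjusted p = 7.4e-06, adjusted p = 0.75 with an estimated correlation). Mbp was at -0.27 ± 0.14. Astrocyte markers had a median of -0.06 with 0 of 21 past the threshold over the list alone (camera adjusted p = 0.0031, adjusted p = 0.75 with an estimated correlation), and Gfap was at -0.26 ± 0.11. The astrocyte call was lost without control vehicle 1 (median -0.04, adjusted p = 0.071), and the myelin median was -0.08 without mutant THC 2 and -0.23 without mutant THC 3. The striatum list was also called, with a median of 1.18, which was -0.59 without mutant THC 3. Its call was lost without mutant vehicle 1 (1.06). Blood genes had a median of 0.19, and their call was lost in 7 of 12 omissions of a library. Camera called 8 lists, 4 up and 4 down, and 5 without control vehicle 1. EdgeR counted 956 genes at an unadjusted p under 0.05, DESeq2 called 3 genes and limma-voom 0.

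Averaged over treatments, mutants differed from controls by Prm1, which was called in all 12 omissions of a library, and by lists that camera called at the preset correlation but not with an estimated one, among them higher myelin, microglia and choroid plexus genes (adjusted p = 0.49, 0.60 and 0.49 with an estimated correlation). Prm1 had 469 counts in 6 mutant libraries and 2 in 6 control libraries, a ratio of 240 (95% exact counting interval 66.1 to 1989, edgeR adjusted p = 6.1e-04). The next genes, none past the threshold, were the glycosyltransferase gene B4galnt4 (log2 fold change -0.34 ± 0.05), Nptxr (-0.60 ± 0.10), the lysosomal protease gene Ctsz (0.40 ± 0.07) and C1rl (1.07 ± 0.18), each with an adjusted p = 0.16. The oligodendrocyte and myelin list had a median of 0.38 and 16 of 19 rose when adjusted over the list alone (camera adjusted p = 5.4e-13, adjusted p = 0.49 with an estimated correlation). Ugt8a was at 0.56 ± 0.13. Microglia markers had a median of 0.12 and 2 of 19 rose over the list alone (camera adjusted p = 5.4e-04, adjusted p = 0.60 with an estimated correlation). C1qa was at 0.17 ± 0.05. Genes of endoplasmic reticulum stress had a median of 0.09 and 5 of 19 rose over the list alone (camera adjusted p = 0.013, adjusted p = 0.54 with an estimated correlation), with the chaperone genes Pdia4 and Hsp90b1 at 0.31 ± 0.08 and 0.29 ± 0.08. Complement genes had a median of 0.17 and 3 of 16 rose over the list alone (camera adjusted p = 0.0047, adjusted p = 0.49 with an estimated correlation). Glutamatergic synapse genes had a median of -0.12 with 0 of 29 past the threshold over the list alone (camera adjusted p = 8.6e-04, adjusted p = 0.54 with an estimated correlation). Beside them the choroid plexus list had a median of 3.20 with 16 of 16 up over the list alone (camera adjusted p = 4.8e-13, adjusted p = 0.49 with an estimated correlation), and Ttr was at 3.84 ± 1.38, while the list's median was 4.91 without control THC 2. The striatum list had a median of 2.28, which was 0.45 without mutant THC 3, and nuclear-retained RNAs one of -0.30 (adjusted p = 0.60 for each with an estimated correlation). The call of nuclear-retained RNAs was lost without control vehicle 2 (-0.17), control THC 2 (-0.25), mutant vehicle 1 (-0.30) or mutant THC 1 (-0.25). With the choroid plexus score as a covariate, chosen after seeing the data, the glutamatergic synapse median was 0.02. Camera called fewer lists with this covariate than without it, and under vehicle the myelin median turned negative with it. The myelin, microglia, complement and endoplasmic reticulum stress medians above are without it. Camera called 15 lists, 13 up and 2 down. EdgeR counted 3345 genes at an unadjusted p under 0.05 where chance gives 790, and called 942 genes without mutant THC 2. DESeq2 called 786 genes (494 higher, 292 lower), and limma-voom 1.

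Mutant THC mice differed from control vehicle mice by Prm1, and genes of endoplasmic reticulum stress were higher as a list by camera at the preset correlation but not with an estimated correlation (adjusted p = 0.60). Prm1 had 210 counts against 1, a ratio of 223 (95% exact counting interval 39.6 to 8853, edgeR adjusted p = 0.024), and its call held in 3 of 12 omissions of a library, without mutant vehicle 3, mutant THC 1 or mutant THC 2 (adjusted p of 0.0063 to 0.41, log2 fold changes of 6.91 to 9.21 over the 12 omissions). Ddit4 was at 37.4 ± 4.49 and 54.4 ± 2.95 CPM (SD, n = 3, log2 fold change 0.54 ± 0.08, adjusted p = 0.29), and Acsf2 (0.63 ± 0.10), the synaptic scaffold gene Caskin1 (-0.50 ± 0.09) and the linker histone gene H1f2 (0.66 ± 0.11) followed, none past the threshold. Genes of endoplasmic reticulum stress had a median of 0.17 and 8 of 19 rose when adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.60 with an estimated correlation). Calr, a calcium-binding chaperone gene, was at 325 ± 19.6 and 412 ± 17.7 CPM (0.34 ± 0.08), Hspa5, which encodes BiP, at 271 ± 21.2 and 353 ± 43.1 CPM (0.38 ± 0.11), and Pdia6 at 0.26 ± 0.07. Glucocorticoid-induced genes had a median of 0.21 and 5 of 20 rose over the list alone (camera adjusted p = 9.0e-04, adjusted p = 0.60 with an estimated correlation). Sgk1 was at 1.01 ± 0.24. The choroid plexus and striatum lists had medians of 4.38 and 3.52, the latter -0.10 without mutant THC 3 (adjusted p = 0.60 and 0.81 with an estimated correlation). Camera called 12 lists, 10 up and 2 down. EdgeR counted 2233 genes at an unadjusted p under 0.05, DESeq2 called 165 genes (46 higher, 119 lower) and limma-voom 0. Prm1 was not among the 165, as DESeq2 gave it a log2 fold change of 7.71 without an adjusted p. Groups did not overlap for 17.5% of genes.

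The THC effects in the 2 genotypes, which share no libraries, ran opposite on balance across 15802 genes, with Pearson's r of -0.30 and Spearman's rho of -0.11, and r was -0.04 without control THC 2. The genotype effects under vehicle and under THC had r of 0.25 and rho of 0.33, and r ranged from 0.03 without mutant THC 1 to 0.58 without control THC 2. It was -0.24 with the choroid plexus score as a covariate and -0.13 with the choroid plexus and striatum scores, alternatives chosen after seeing the data. Genes are not independent replicates, so these values carry no p. Prm1 was the 1 gene called in both genotype comparisons, each of which called 1 gene. The THC effect in mutants and the genotype effect under vehicle share the mutant vehicle libraries with opposite signs, so that opposite directions of complement or choroid plexus genes in these 2 comparisons are partly built in. The lists that camera called in none of the 8 comparisons were the endocannabinoid system (medians -0.07 to 0.00, 16 genes), serine and glycine metabolism (-0.10 to 0.08, 13 genes), progenitors and immature neurons (-0.03 to 0.13, 11 genes), circadian clock genes (-0.08 to 0.06, 21 genes) and heat shock genes (0.00 to 0.08, 15 genes).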

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

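For 19 of 36 gene lists the THC effect differed between mutant and control mice by the interaction test itself (camera with the preset correlation), 8 higher and 11 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.078). The counts over other splits were planned before the results were seen. Groups of 3 were not tested for single libraries that stand apart.

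The median interaction log2 fold change was -0.80 for complement, -0.51 for reactive astrocyte genes, -0.29 for interferon response, -0.29 for NF-kB targets and subunits, -0.35 for the prostanoid and leukotriene pathway and -0.22 for glucocorticoid-induced genes. Among lists of other tissues and vessels it was -4.60 for choroid plexus, -0.81 for mural and meningeal cells, -0.56 for blood and 2.69 for striatum. Neuronal and glial lists had medians of -0.49 (dentate granule neurons), -0.48 (CA2 and CA3 pyramidal neurons), 0.50 (CA1 pyramidal neurons), 0.36 (neocortex layers), 0.21 (interneuron markers), 0.13 (GABA receptors and transport), 0.12 (glutamatergic synapse), 0.12 (oligodendrocyte and myelin) and 0.05 (DISC1 and its binding partners).

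Without mutant THC 3 camera called the striatum list in the opposite direction (median -1.0, adjusted p = 0.011). The myelin call was lost without control vehicle 1 or 2, control THC 1 or 3, mutant vehicle 1 or 2, or mutant THC 1 or 3, with medians from -0.03 to 0.12. The call of DISC1 partners was lost without control vehicle 1 or 3, control THC 2, mutant vehicle 1 or 3, or mutant THC 2 or 3, with medians from 0.02 to 0.06. Interneuron markers lost theirs without control vehicle 1, control THC 3, mutant vehicle 1 or 3, or mutant THC 1 (0.14 to 0.21). Glutamatergic synapse genes lost theirs without control THC 2 (0.08), mutant vehicle 3 (0.04) or mutant THC 2 (-0.02), and GABA genes without control THC 2 (0.12) or mutant THC 2 (0.14). Dentate granule and CA2 and CA3 markers lost theirs without control THC 3 (-0.21 and -0.24) or mutant THC 1 (-0.35 and -0.45), and neocortex layers without mutant THC 1 (0.10). Other medians moved with the call kept: CA1 markers to 0.25 without control THC 3 and 0.32 without mutant THC 1, neocortex layers to 0.21 without control vehicle 3 and 0.21 without mutant vehicle 3, and dentate granule and CA2 and CA3 markers to -0.82 and -0.73 without mutant THC 2. GABA genes moved to 0.21 without control THC 1, glutamatergic synapse genes to 0.04 without control vehicle 3, and DISC1 partners to 0.08 without control THC 3 and 0.09 without mutant THC 1. Myelin genes moved to 0.21, 0.24, 0.19 and 0.29 without control vehicle 3, control THC 2, mutant vehicle 3 and mutant THC 2. The choroid plexus median was -1.0 without control THC 2, the mural and meningeal one -0.53 without mutant vehicle 1, the glucocorticoid one -0.11 without control THC 1 and the NF-kB one -0.19 without mutant vehicle 3. The prostanoid median was -0.19, -0.19, -0.22 and -0.21 without control THC 2, mutant vehicle 3, mutant THC 2 and mutant THC 3.

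Of 100 splits of the libraries, the real one included, 4 gave as many lists for the interaction as the real 19, and the highest other gave 21, a share under 0.05. The median of the other splits was 11 lists. The splits exchanged vehicle and THC libraries within each genotype. They thus stand for no THC effect in either genotype, not for equal THC effects, so this share does not decide on an interaction. For single genes the real count was 0, which each of the 100 splits must reach, so the count of splits (100, highest other 1) decides nothing.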

How the results depend on the processing

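The alternatives with the choroid plexus or striatum score and without mutant vehicle 3 and mutant THC 3 were chosen after seeing the data. No paired analysis was possible because the labels give no number that recurs between groups. Depth limits Prm1, whose control counts were 0 or 1. Unless stated, the cause was not tested.

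In the order THC in control mice, THC in mutant mice, genotype under vehicle, genotype under THC, interaction, THC averaged, genotype averaged and mutant THC against control vehicle, edgeR called 0, 0, 1, 1, 0, 0, 1 and 1 genes. DESeq2 called 11, 3, 768, 7, 32, 3, 786 and 165, the last without Prm1, for which it gave no adjusted p. In simulated data DESeq2 called 29 to 41 unchanged genes and edgeR 4 to 9. DESeq2 recovered 122 to 178 of the 200 changed genes. For the interaction it recovered 122, and edgeR 12, 40 and 55 of the 1.5-fold, 2-fold and 4-fold changes. The simulated libraries lacked the differences in choroid plexus and striatum markers seen here, so these counts may not hold for the real libraries. Limma-voom called 0 for genotype under vehicle, genotype under THC and mutant THC against control vehicle, and with sample weights 0 for genotype under THC. A mean of 5 CPM, which removes Prm1, left 0 in the 4 comparisons that called it. With only the 2 groups compared the counts were 523 for genotype under vehicle, 0 under THC and 0 for mutant THC against control vehicle. With the first residual principal component as a covariate they were 913 for genotype under vehicle, 6 under THC, 1 for the interaction, 1337 for genotype averaged and 18 for mutant THC against control vehicle. Genotype under vehicle and mutant THC against control vehicle fell to 0 and 0 with the choroid plexus score, and to 0 and 0 with both scores. Without mutant vehicle 3 and mutant THC 3, genotype under vehicle, under THC and mutant THC against control vehicle had 0, 0 and 0.

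Camera with an estimated correlation called 0 lists in each of the 8 comparisons. Fry called 0, 0, 3, 0, 2, 0, 0 and 0. For genotype averaged, camera called 7 lists with the choroid plexus score and 9 with both scores.

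With the choroid plexus score as a covariate, the choroid plexus median was -0.06 for THC in mutants and -0.03 for genotype under THC. The score is made from that list, so small values for the list and its member Ttr follow from the fit and test nothing. Glutamatergic synapse medians were 0.01 for genotype under vehicle, -0.04 for the interaction, 0.02 for genotype averaged and 0.03 for mutant THC against control vehicle. Myelin medians were -0.10 for genotype under vehicle and -0.02 for mutant THC against control vehicle, and that of DISC1 partners was 0.00 for the interaction. Trf was at -0.08 for genotype under vehicle, Srr at -0.04 and Rela at 0.04 for the interaction. For genotype averaged Srr was at 0.09, Ptgs2 at 0.04, Rela at -0.04 and Ttr at -0.07. The correlation of the genotype effects was -0.24.

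With both scores the choroid plexus medians were -0.08 for THC in mutants and -0.01 for genotype under THC. Striatum medians were 0.01 for THC in mutants, -0.11 for the interaction and -0.02 for THC averaged. Small values for both lists and their members Ttr and Gpr6 again follow from the fit and test nothing. Glutamatergic synapse medians were 0.01 for genotype under vehicle, -0.04 for the interaction, 0.01 for genotype averaged and -0.01 for mutant THC against control vehicle. Myelin medians were -0.08 for genotype under vehicle and -0.09 for mutant THC against control vehicle, and that of DISC1 partners was -0.02 for the interaction. Trf was at -0.04 for genotype under vehicle and Gpr6 at -0.20 for genotype under THC. Srr was at -0.07 and Rela at 0.03 for the interaction, and Disc1 at 0.01 for THC averaged. For genotype averaged Srr was at 0.08, Cnr1 at -0.02, Ptgs2 at 0.09, Nfkb1 at 0.00, Rela at -0.04 and Ttr at -0.12. The correlations were -0.21 for the THC effects and -0.13 for the genotype effects.

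Without mutant vehicle 3 and mutant THC 3 the thalamus median was 0.07 for THC in mutants, against -0.52 with all libraries. The thalamus call was lost without mutant vehicle 3 (-0.18), mutant THC 1 (-0.40) or mutant THC 3 (-0.30) alone. Striatum medians were 0.01 for THC averaged, -0.03 for genotype averaged and -0.10 for mutant THC against control vehicle. Gpr6 was at -0.10 for genotype under THC, Disc1 at 0.08 and Ptgs2 at 0.09 for THC averaged, and the THC effects correlated at -0.17. With no low-count filter Rela was at 0.00 for the interaction and 0.00 for genotype averaged, Nfkb1 at 0.00 for THC averaged and Disc1 at 0.00 for genotype averaged, and the correlations were -0.06 and 0.11. Disc1 for genotype averaged was at -0.02 with limma-voom and -0.01 with the residual component, and Nfkb1 for THC averaged at 0.01 with upper-quartile factors.

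Leaving out each library gave 0 to 3 genes for THC in mutants (3 without mutant THC 1), 0 to 6 for genotype under vehicle (6 without mutant THC 1) and 0 to 2 for genotype under THC. It gave 0 to 10 for the interaction (10 without mutant THC 1), 1 to 942 for genotype averaged (942 without mutant THC 2) and 0 to 1 for mutant THC against control vehicle. Lists called ranged from 6 to 15 for genotype under THC and 5 to 12 for THC averaged. Striatum medians ranged from -0.95 to 3.56 for THC in mutants, -1.0 to 3.66 for the interaction, -0.59 to 1.74 for THC averaged and -0.10 to 4.07 for mutant THC against control vehicle, each lowest without mutant THC 3. Choroid plexus ranged from -0.22 to 4.44 for genotype under THC, glutamatergic synapse from -0.02 to 0.15 and myelin from -0.03 to 0.29 for the interaction, and neocortex layers from -0.51 to 0.01 for mutant THC against control vehicle. Ttr ranged from -0.03 to 5.61 for THC in controls (lowest without control THC 2) and Gpr6 from -0.09 to 5.92 for genotype under THC (lowest without mutant THC 3). Gfap ranged from -0.30 to 0.03 and Rela from -0.05 to 0.02 for the interaction. For THC averaged Disc1 ranged from -0.16 to 0.10, Ptgs2 from -0.20 to 0.08 and Nfkb1 from -0.02 to 0.02. For genotype averaged Disc1 ranged from -0.13 to 0.14, Srr from -0.04 to 0.02 and Rela from -0.02 to 0.03. The correlations ranged from -0.33 to -0.04 for the THC effects and 0.03 to 0.58 for the genotype effects. Over all alternatives and omissions, 17 of 107 list results and 16 of 118 gene results changed sign at least once. They include lists entered as covariates and members of these lists, for which that fit fixed a small value of either sign.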

Other observations

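The tests of a transgene, of exchanged labels, of the genotype difference in the choroid plexus score and of the choroid plexus score as a covariate were chosen after the results were seen.

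Blood genes were higher in mutants as a list. Averaged over treatments their median log2 fold change was 0.50 and 4 of 6 rose when adjusted over the list alone (camera adjusted p = 4.6e-05, adjusted p = 0.49 with an estimated correlation). Under vehicle the median was 0.79, again with 4 of 6 (camera adjusted p = 1.6e-06, adjusted p = 0.27 with an estimated correlation). Antioxidant and metallothionein genes had a median of 0.17 under vehicle and 2 of 17 rose over the list alone (camera adjusted p = 0.0017, adjusted p = 0.27 with an estimated correlation).

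For THC in control mice camera called the lists of the hippocampal subfields at the preset correlation and not with an estimated one, and the lists were not tested against each other. Dentate granule neuron markers had a median of 0.35 with 10 of 10 above 0, CA2 and CA3 markers one of 0.28 with 9 of 9 above 0, and CA1 markers one of -0.24 with 5 of 5 below 0 (camera adjusted p = 5.0e-04, 0.0089 and 0.0031, adjusted p = 0.38, 0.47 and 0.38 with an estimated correlation). Neocortex layer markers had a median of -0.27 with 0 of 11 past the threshold over the list alone (camera adjusted p = 0.0011, adjusted p = 0.32 with an estimated correlation), -0.44 without control vehicle 2 and -0.12 without control THC 3. The CA1 median was -0.42 without control THC 1 and -0.37 without control THC 2, and the dentate median 0.54 without control THC 1. Without control THC 3 all 3 subfield calls were lost, with medians of 0.10, 0.08 and -0.12, and the CA2 and CA3 call was also lost without control vehicle 1 (0.21). Oligodendrocyte precursor markers had a median of -0.22 and 2 of 8 fell over the list alone (camera adjusted p = 0.0012, adjusted p = 0.32 with an estimated correlation). Their median was -0.14 without control vehicle 1 and -0.13 without control vehicle 2.

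Prm1 had 35 to 111 counts in each of the 6 mutant libraries and 0 or 1 in the 6 control libraries. RNA from testis would bring other spermatid transcripts, and 9 of these summed to 7 counts in the mutant libraries, against 469 of Prm1, which argues against it. A transgene that carries a Prm1 sequence may be the source, as protamine-1 sequence is used in some transgene cassettes. Prm1 above 3 counts in 6 of 6 mutant libraries restates the pattern and does not test this, and the labels do not describe the construct, so it stays open.

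The choroid plexus list was high in 5 of 6 mutant and 1 of 6 control libraries. Choroid plexus tissue in the dissected sample would move its genes together, and the SD of log2 member over Ttr (median 1.02) was 0.28 of the SD of log2 Ttr (3.61), which is consistent with such tissue. An exchange of the labels of control THC 2 and mutant THC 2 would leave mutant THC 2 without Prm1, and it had 35 counts. Genotype stays open, with a list score difference of 3.27 (exact permutation within treatment, adjusted p = 0.16 over the lists). Exchanging these 2 libraries gave 1281 genes for the genotype effect averaged over treatments and 204 under THC, which points to a structure of the libraries: this exchange parts the 6 with high from the 6 with low choroid plexus scores, so these counts restate the pattern and are no separate evidence.

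The complement and reactive astrocyte lists had medians of 0.67 and 0.30 in mutant vehicle mice and were called by camera at the preset correlation but not with an estimated one (adjusted p = 0.18 and 0.23). For reactive astrocyte genes the median was 0.34 with the choroid plexus score as a covariate and 0.33 with the mural and meningeal score. The camera call was kept with each (adjusted p = 1.8e-09 and 0.018 at the preset correlation). This cannot exclude either tissue, since each score was entered alone and both differed between the vehicle groups. The choroid plexus score was 0.56 ± 0.60 in control and 5.64 ± 0.90 in mutant vehicle, and the mural and meningeal score 4.01 ± 0.08 and 4.59 ± 0.11. For complement genes it was 0.21 and 0.22 in the same order, so a share from choroid plexus or meninges and a change in brain cells cannot be told apart. The lists share Serping1 and C3. An effect of the mutation on brain cells remains untested against other sources.

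In the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For genes the real and highest other counts were 0 and 0 for THC in control mice (10 splits as large), 0 and 0 for THC in mutant mice (10, which a real count of 0 fixes in both cases), 1 and 0 for genotype under vehicle (1), 1 and 204 for genotype under THC (3), and 1 and 0 for mutant THC against control vehicle (1). For lists they were 15 and 18 (3 splits as large), 10 and 18 (7), 17 and 21 (3), 11 and 13 (4), and 12 and 15 (4) in the same order. With 100 splits, the 1 gene of the averaged genotype effect was matched by 4, a share under 0.05, with 1281 as the highest other. Its 15 lists were matched by 29 splits (highest other 23), and the 8 lists of the averaged THC effect by 87 (highest other 19), so chance is not excluded for these 2 counts. The averaged THC effect called 0 genes, which each of the 100 splits must reach (highest other 1), so that count decides nothing. At an unadjusted p under 0.05, the real and highest other counts were 1106 and 1165 for THC in control mice, 906 and 2130 for THC in mutant mice, 2815 and 880 for genotype under vehicle, 1419 and 2807 for genotype under THC, and 2233 and 2719 for mutant THC against control vehicle. With 100 splits they were 1041 and 2206 for the interaction and 956 and 2205 for THC averaged, matched by 27 and 26 splits, so chance is not excluded for these. For genotype averaged they were 3345 and 4190, matched by 2 splits, a share under 0.05. The split with 4190 exchanged control THC 2 and mutant THC 2, which parts the libraries by choroid plexus score. This share therefore does not tell genotype apart from that score.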
